A study of Danio rerio with 4 samples.

How the data were processed

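RNA from pools of 10 larvae at 5 dpf was sequenced after ribosomal RNA removal, per the labels, giving 2 libraries of *uhrf1* mutants and 2 of phenotypically normal siblings. The deposited values are raw counts per RefSeq accession and raw counts per repeat name. Per the submitters' processing notes, Bowtie2 2.1.0, HTSeq and DESeq2 were used with genome build GRCz10, and the notes give these tools no role or order. The annotation, the filters, the handling of reads that map to several places and the strand setting are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical copies can be split between them or dropped. The gene table held 15171 rows, of which 14472 were given a symbol by matching the accession to a RefSeq table of assembly GRCz12tu, used for names only, so no coordinates are given. A symbol had more than 1 row in 293 cases (645 rows), and lists used the row with the most counts. The repeat table held 1821 names, put into classes by their names.

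Groups and replicate numbers come from the sample titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM scaling, glmQLFit and glmQLFTest on mutant against sibling, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. That of a list's median came from the spread across the list's genes. Those genes are not independent replicates, so it does not measure the spread between pools. Repeats were scaled by the gene table's effective library sizes, so that a change in all repeats would show. The 28 gene lists (939 symbols, 794 matched and 139 not matched; the rest merged onto a gene already in the list) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over lists with at least 5 genes. Estimated correlations and fry, which asks whether a list's genes move one way on balance and compares them with no other genes, were run beside it. The lists, tests and alternatives were fixed before the data were examined, apart from those named as added.

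The genes named were *uhrf1*, the 12 with the largest change in each direction among those past the threshold with a mean of at least 5 CPM and both mutants on the same side of both siblings (clone-style names passed over), and up to 4 genes with the lowest p from each list. Repeats followed the same rule with up to 8 per direction and simple repeats passed over.

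One count was worth 0.201 CPM in sibling 1, 0.334 in sibling 2, 0.110 in mutant 1 and 0.303 in mutant 2, before TMM scaling. A floor of 3 counts over the group was used for a group with no counts. Intervals and floors cover counting error only. The biological coefficient of variation was 20.0% for genes. Replicates were not duplicates of each other: the chi-square per degree of freedom over genes was 17.3 for the siblings and 15.1 for the mutants.

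The test was checked on simulated data, with 5 sets of counts for the 12786 genes of the mutant against sibling comparison drawn from the real means, dispersions and library sizes, and 200 genes changed in each. edgeR found 36.7% of genes changed 2-fold, 96.7% of those changed 4-fold and 99.7% of those changed 8-fold, all with the right sign, and 9.40% of its calls were false, above the nominal rate. For the 1029 repeats, with 200 changed in each set, it found 21.8%, 84.5% and 98.8%, with 2.71% of calls false. Repeats were drawn independently, without the shared repeat excess of sibling 2. That rate therefore does not cover a shift shared by the repeats of a library. A planted list of 30 genes raised 2-fold was called by camera in 5 of 5 simulations with the preset correlation and in 0 of 5 with an estimated one, and no unchanged list was called. Genes were drawn independently of each other there. The simulation therefore does not check camera's false calls for lists whose genes vary together.

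Alternatives were DESeq2 1.42.0, limma-voom, other scalings and count filters (no filter, or at least 50 counts in 2 libraries), a 2-fold criterion, the replicate number as a block, leaving out each library, and other denominators and scalings for repeats. All columns of both tables belong to the 4 samples and were used.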

Results

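Whole zebrafish larvae (*Danio rerio*) carrying the hi272 allele of *uhrf1* were compared with their phenotypically normal siblings at 5 days post fertilization (dpf) by sequencing of ribosome-depleted total RNA. Uhrf1 binds hemimethylated DNA and recruits the maintenance DNA methyltransferase Dnmt1 at replication, and the comparison asks how genes and repeats are expressed in the mutants. Each library was made from a pool of 10 larvae, and there were 2 mutant and 2 sibling libraries. Per the labels, the sibling pools mixed wild-type and heterozygous larvae. Counts assigned to genes came to 4981004 in sibling 1, 2996676 in sibling 2, 9100665 in mutant 1 and 3299449 in mutant 2. Counts assigned to repeats came to 692687, 823100, 1701711 and 643328 in the same order. One group of 2 against another cannot give an exact two-sided permutation p under 0.333, so the tests below are models fitted across all genes or repeats. The labels name 2 clutches without tying a clutch to a library, and the p-values measure the spread between these pools only. Expression is given below in CPM, a count relative to the library's total after TMM scaling, folds as mutant over sibling, and the standard error (SE) of each log2 fold change on the log2 scale.

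*uhrf1* itself (NM_213077) stood at 21.4 and 46.8 CPM in siblings 1 and 2 and at 33.3 and 24.2 CPM in mutants 1 and 2. Its log2 fold change was -0.21 (SE 0.35, edgeR adjusted p = 0.765), and without sibling 2 it was 0.44. The 2 groups overlapped, so the *uhrf1* count does not check the labels, and "mutant" below means a library labelled mutant. Counts per accession do not separate normal from disrupted transcripts of the locus.

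Interferon and inflammatory genes rose and exocrine pancreas genes fell in the mutants. Of 12786 genes tested with edgeR's quasi-likelihood test, 1070 passed a Benjamini-Hochberg adjusted p of 0.05, of which 585 were higher and 485 lower in mutants. At least 8-fold changes were seen for 97 genes that were higher and 61 that were lower. The ubiquitin-like antiviral modifier *isg15* rose from 13.5 and 25.5 CPM in the siblings to 1572 and 1681 CPM in the mutants (log2 fold change 6.39, SE 0.46, edgeR adjusted p = 5.05e-05). The pancreatic carboxypeptidase gene *cpa1* fell from 597 and 176 CPM to 28.1 and 4.60 CPM (log2 fold change -4.46, SE 0.73, edgeR adjusted p = 0.00446). Both mutants lay above both siblings for 28.0% of genes tested and below both for 26.9%, and chance gives 33.3% for the 2 directions together. Without mutant 2 the counts were 333 higher and 243 lower, and without sibling 2, 805 higher and 754 lower.

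Among the genes with the largest rises, several belong to interferon signalling and antigen presentation. *socs1b*, a feedback inhibitor of cytokine signalling, had no counts in either sibling and 11.8 and 18.4 CPM in the mutants, which is at least 34.6-fold higher when 3 counts over the sibling group are taken as the floor. The MHC class I gene *mhc1uba* rose from 0.676 and 1.57 CPM to 57.9 and 252 CPM. The antiviral GTPase genes *mxe* and *mxc* rose by log2 fold changes of 6.41 (SE 0.43) and 6.15 (SE 0.38). *cd83*, a surface protein of activated antigen-presenting cells, rose by 6.32 (SE 0.30), the chemokine gene *cxcl18b* by 6.12 (SE 0.29), the MHC class II invariant chain gene *cd74a* by 5.92 (SE 0.29) and the interferon signal transducer *stat1b* by 5.84 (SE 0.30), all on the log2 scale. The proteasome subunit genes *psmb8a* and *psmb13a* rose by 5.50 (SE 0.58) and 5.36 (SE 0.47) on that scale. *ifit8* had 2 counts in the siblings together, and its ratio of summed counts was 71.2 with an exact 95% interval of 19.5 to 592. Mx genes are close copies whose reads the counting could split, so their single values are uncertain.

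**Figure D1:**
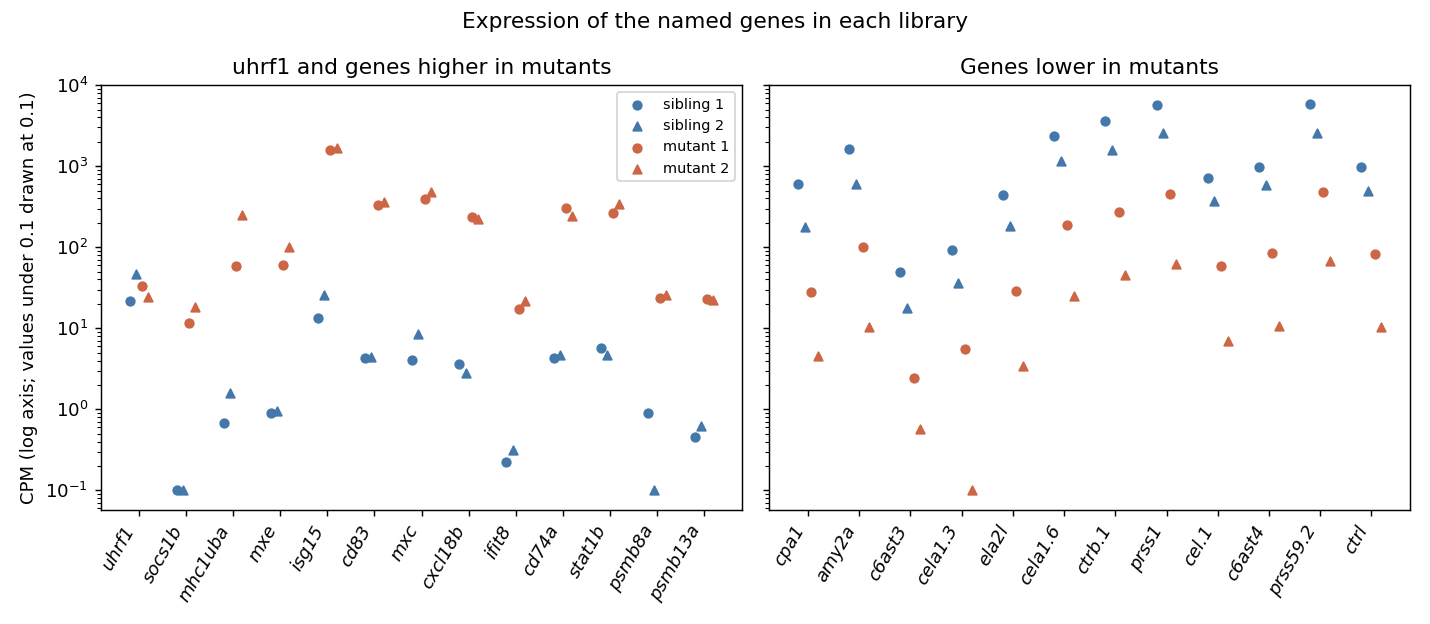
CPM on a log axis for *uhrf1* and the genes with the largest changes, 1 point per library, with circles for replicate 1, triangles for replicate 2, blue for siblings and orange for mutants. *isg15* lies at 1572 and 1681 CPM in the mutants against 13.5 and 25.5 CPM in the siblings, and the digestive enzyme genes are lower in mutant 2 than in mutant 1.

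The interferon and antiviral list moved as a group. Of its 40 genes tested, 31 rose and 9 did not pass, and 34 rose when adjusted over the list alone. Its median log2 fold change was 3.30, and the set test camera, with a correlation preset at 0.01, gave an adjusted p of 1.15e-30 (adjusted p = 0.241 with an estimated correlation). *stat1b* and *b2m*, a light chain gene of MHC class I, had the lowest p in the list, and *b2m* rose from 5.86 and 7.23 CPM to 252 and 179 CPM. The far more abundant *b2ml*, outside the list, stood at 925 and 709 CPM in the siblings and 1725 and 1237 CPM in the mutants. Its log2 fold change was 0.86 (SE 0.36) and it did not pass (edgeR adjusted p = 0.178). Of 22 genes for inflammatory cytokines and the acute phase, 18 rose (18 adjusted over the list alone), with a median of 1.95 (camera adjusted p = 6.63e-15, adjusted p = 0.178 with an estimated correlation). They included the matrix metalloproteinase gene *mmp9* (log2 fold change 3.22, SE 0.26) and the cytokine gene *il34* (3.72, SE 0.31).

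Markers of blood cells moved in different directions. Of these lists, fry passed neutrophil markers as higher (adjusted p = 0.0127) and lymphoid markers as lower (adjusted p = 0.0405). It did not pass macrophage and leukocyte markers (adjusted p = 0.947) or erythroid markers (adjusted p = 0.109). Of 8 neutrophil markers, 3 rose (3 adjusted over the list alone), among them the myeloperoxidase gene *mpx* (log2 fold change 2.22, SE 0.24), with a list median of 0.49 (camera adjusted p = 0.00417, adjusted p = 0.307 with an estimated correlation). Without mutant 1, 1 neutrophil marker was higher. Of 11 macrophage and leukocyte markers, *mpeg1.2* (2.06, SE 0.23) and *ctss2.1* (1.68, SE 0.33) rose while *mpeg1.1* (-1.58, SE 0.31) and *coro1a* (-1.62, SE 0.34) fell, with 2 higher and 3 lower adjusted over the list alone. Without mutant 1 the macrophage list's median turned from -0.17 to 0.16, it was -0.28 without sibling 1 and -0.48 without mutant 2, and the call of *mpeg1.1* was lost without mutant 1 (edgeR adjusted p = 0.0688) and that of *coro1a* without mutant 2 (edgeR adjusted p = 0.0741). Of 6 lymphoid and thymus markers, 1 fell, the recombinase gene *rag1* (log2 fold change -2.32, SE 0.52; 1 adjusted over the list alone), a call lost without sibling 2, without mutant 1 and without mutant 2, while the lymphoid list as a whole passed without mutant 2 (camera adjusted p = 0.0124). Of 15 erythroid markers, 3 fell (3 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.0136, adjusted p = 0.315 with an estimated correlation), and they included the anion exchanger gene *slc4a1a* (-1.31, SE 0.25). Without mutant 1 the erythroid call was lost (median -0.31, camera adjusted p = 0.139), and 1 erythroid gene was lower without mutant 1 and 1 without mutant 2.

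Lists of replication and stress genes rose in camera with the preset correlation. Of the lists in this paragraph, fry passed only p53 targets (adjusted p = 0.0405). It did not pass S phase (adjusted p = 0.178), mitosis (adjusted p = 0.473), apoptosis (adjusted p = 0.0565), stress responses (adjusted p = 0.0681) or ribosome biogenesis (adjusted p = 0.109). Of 46 genes of DNA replication and S phase, 13 rose, and 24 rose adjusted over the list alone, with a median log2 fold change of 0.95 (camera adjusted p = 1.13e-10, adjusted p = 0.422 with an estimated correlation). The helicase subunit genes *mcm5* (1.32, SE 0.25) and *mcm4* (1.17, SE 0.23) were among them. Of 40 genes of mitosis and cytokinesis, 3 rose, namely *cdc20*, *kif23* and *ncapg* (3 adjusted over the list alone), and 39 had a fold change above 0, with a median of 0.74 (camera adjusted p = 5.54e-07, adjusted p = 0.668 with an estimated correlation). Both counts rested on single libraries: without mutant 2 they were 3 and 0, without sibling 2 they were 21 and 29. The mitosis median was 0.24 without sibling 1 (camera adjusted p = 0.0792), 1.48 without sibling 2 and 0.46 without mutant 2. Of 38 p53 target and DNA damage genes, 8 rose (13 higher and 2 lower adjusted over the list alone), with *pmaip1* (2.43, SE 0.29), a pro-apoptotic BH3-only gene, and *rps27l* (2.29, SE 0.28) among them, and a median of 0.61 (camera adjusted p = 0.000158, adjusted p = 0.241 with an estimated correlation). Of 28 apoptosis genes, 7 rose (9 adjusted over the list alone), including *casp8* (2.00, SE 0.23) and *bcl2l11* (2.46, SE 0.36), with a median of 0.41 (camera adjusted p = 0.000545, adjusted p = 0.307 with an estimated correlation); *casp8* and *pmaip1* stand in both lists. Without sibling 2 the apoptosis median was 0.26 and 1 gene was lower. Of 33 genes of the unfolded protein and integrated stress responses, 14 rose (19 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 1.88e-08, adjusted p = 0.307 with an estimated correlation), led by the transcription factor gene *atf3* (3.34, SE 0.23). Without mutant 2, 6 genes of this list were higher. Of 39 ribosome biogenesis genes, 4 rose, namely *dkc1*, *fbl*, *nop2* and *nhp2* (4 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 9.18e-05, adjusted p = 0.392 with an estimated correlation), and none passed without mutant 2. Of these, *nop2* and *nhp2* were also lost with DESeq2 and without mutant 1, *dkc1* and *nop2* without sibling 1, and *nhp2* without sibling 2.

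Digestive organ markers fell in camera with the preset correlation. Of the lists in this paragraph, fry passed only intestinal epithelium (adjusted p = 0.0282). It did not pass exocrine pancreas (adjusted p = 0.115), endocrine pancreas (adjusted p = 0.947) or hepatocytes (adjusted p = 0.0709). All 20 exocrine pancreas markers tested were lower in mutants, 20 also adjusted over the list alone, with a median log2 fold change of -3.86 (camera adjusted p = 1.46e-16, adjusted p = 0.327 with an estimated correlation). The 12 named genes with the largest falls, *cpa1*, *amy2a*, *c6ast3*, *cela1.3*, *ela2l*, *cela1.6*, *ctrb.1*, *prss1*, *cel.1*, *c6ast4*, *prss59.2* and *ctrl*, are digestive hydrolase genes or their relatives, and had log2 fold changes between -4.46 and -3.92. Trypsin gene *prss1* went from 5696 and 2558 CPM in siblings 1 and 2 to 452 and 63.0 CPM in mutants 1 and 2. Mutant 2 set much of the size: the list median was -5.95 without mutant 1 and -3.07 without mutant 2, when 16 of the 20 passed and *prss1* (edgeR adjusted p = 0.0894) and *prss59.2* (edgeR adjusted p = 0.0995) did not. The trypsin, chymotrypsin and elastase families each can hold close copies whose reads the counting could split. Identity between copies was not measured, and the single values of such copies are uncertain. Of 12 endocrine pancreas markers, the glucagon gene *gcgb* rose (1.48, SE 0.35) and *isl1a* fell (-0.77, SE 0.21), with 1 higher and 2 lower adjusted over the list alone. Both endocrine calls were lost without mutant 1, without mutant 2 and with DESeq2, that of *gcgb* also without sibling 2 and that of *isl1a* without sibling 1 and with library totals alone. The endocrine list's median was 0.18 and its mean 0.06, and camera, which did not pass it, gave the opposite direction to the median, which was 0.37 without sibling 1, 0.02 without sibling 2 and -0.10 without mutant 1. Of 18 intestinal epithelium markers, 13 fell (14 lower and 1 higher adjusted over the list alone), with a median of -1.56 (camera adjusted p = 1.67e-10, adjusted p = 0.178 with an estimated correlation). The peptide transporter gene *slc15a1b* (-2.89, SE 0.36) and the fatty acid binding protein gene *fabp2* (-2.17, SE 0.25) were among them. Of 33 hepatocyte markers, 12 fell and 3 rose (18 lower and 4 higher adjusted over the list alone), with a median of -0.99 (camera adjusted p = 9.29e-07, adjusted p = 0.307 with an estimated correlation), and the urate oxidase gene *uox* fell by 2.91 (SE 0.31) on the log2 scale.

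Eye markers fell as well, with fry passing photoreceptors (adjusted p = 0.0127) but not lens (adjusted p = 0.0709). Of 44 lens markers, mostly crystallin genes, 42 were lower in mutants (42 adjusted over the list alone), with a median log2 fold change of -2.92 (camera adjusted p = 2.27e-34, adjusted p = 0.307 with an estimated correlation). *cryba2a* went from 870 and 574 CPM to 97.2 and 91.4 CPM, and the beaded filament gene *bfsp2* from 171 and 109 CPM to 27.0 and 25.3 CPM. Gamma-crystallin genes of the *crygm2d* group are near-identical copies. Of 41 photoreceptor markers, 16 fell (29 lower and 2 higher adjusted over the list alone), with a median of -0.995 (camera adjusted p = 2.51e-12, adjusted p = 0.178 with an estimated correlation), among them the cone arrestin genes *arr3a* (-1.65, SE 0.23) and *arr3b* (-1.78, SE 0.27). Without mutant 2, 7 photoreceptor genes were lower, and without mutant 1, 10 were.

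Among markers of other tissues, germline genes and sterol synthesis genes, camera passed none of the lists. Of 32 skeletal muscle markers, 1 fell, *tnni2a.1* (log2 fold change -1.57, SE 0.34; 1 adjusted over the list alone), and the median was 0.11. Neither the 12 heart markers nor the 22 neuronal markers held a gene past the threshold in edgeR, DESeq2 or limma-voom, or in edgeR adjusted over the list alone, and 2 and 3 of them had an unadjusted edgeR p under 0.05. Of 16 glia and myelin markers, *slc1a3b* and *s100b* rose and 3 fell, *plp1b* and *rlbp1a* among them, with 3 and 3 adjusted over the list alone. Of 26 cartilage and bone markers, *matn3b* rose and *mia* and *col10a1a* fell (1 and 2 adjusted over the list alone). Of 24 skin keratinocyte markers, *cldne* rose and *krt92*, *krt97* and *cyt1l* fell (1 and 3 adjusted over the list alone). The 8 germline and piRNA pathway genes and the 25 genes of sterol synthesis held no call with edgeR, DESeq2 or limma-voom, nor with edgeR adjusted over the list alone, and 0 and 4 of them had an unadjusted edgeR p under 0.05. Of 43 germline symbols, 30 were matched and only those 8 passed the count filter, so most of that list was not tested. Leaving out 1 library changed several of these results. Without sibling 2, camera passed cartilage and bone (adjusted p = 0.00735) and sterol synthesis (adjusted p = 0.00120) as higher and skin (adjusted p = 0.0255) as lower, and 6 cartilage and 5 sterol genes were higher and 6 skin genes lower. The sterol median was 0.30, with -0.06 without sibling 1 and 0.79 without sibling 2. Without mutant 1 it passed cartilage and bone as higher (adjusted p = 0.0264), and without mutant 2 neuronal markers as lower (adjusted p = 0.0251), when 1 glia and 1 skin marker were lower. The rise of *matn3b* was lost with DESeq2 (adjusted p = 0.0579) and without sibling 2, mutant 1 or mutant 2 (edgeR adjusted p = 0.0777, 0.0861 and 0.112), and that of *cldne* without mutant 2. The falls of *tnni2a.1* (edgeR adjusted p = 0.0741), *mia*, *rlbp1a*, *krt97* and *cyt1l* were lost without mutant 2 and those of *col10a1a* and *cyt1l* without mutant 1, when 2 muscle genes were lower. The muscle median was 0.37 without sibling 1, -0.09 without sibling 2, -0.12 without mutant 1 and 0.22 without mutant 2, and skin had 4 genes higher without sibling 1.

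Among chromatin genes, 2 of the 14 genes of the DNA methylation machinery rose (2 adjusted over the list alone), *dnmt3bb.2* (log2 fold change 1.75, SE 0.35, edgeR adjusted p = 0.0122) and *dnmt1* (1.07, SE 0.28, edgeR adjusted p = 0.0441). The list's median was 0.21 (camera adjusted p = 0.131, and adjusted p = 0.0157 without sibling 2), with 0.50 without sibling 2, 0.35 without mutant 1 and 0.14 without mutant 2. Without sibling 2, 3 members were higher and without sibling 1, 1 was higher and 1 lower. No member passed edgeR's test without mutant 2 (*dnmt1* adjusted p = 0.268, *dnmt3bb.2* adjusted p = 0.0553), and without sibling 1 *dnmt1* did not (edgeR adjusted p = 0.0734). None of 27 heterochromatin and Polycomb genes passed in edgeR, DESeq2 or limma-voom, or in edgeR adjusted over the list alone, and 2 had an unadjusted edgeR p under 0.05, while 2 were higher without sibling 2. Their median was 0.17, with 0.03 without sibling 1, 0.30 without sibling 2, 0.25 without mutant 1 and 0.07 without mutant 2.

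**Figure D2:**
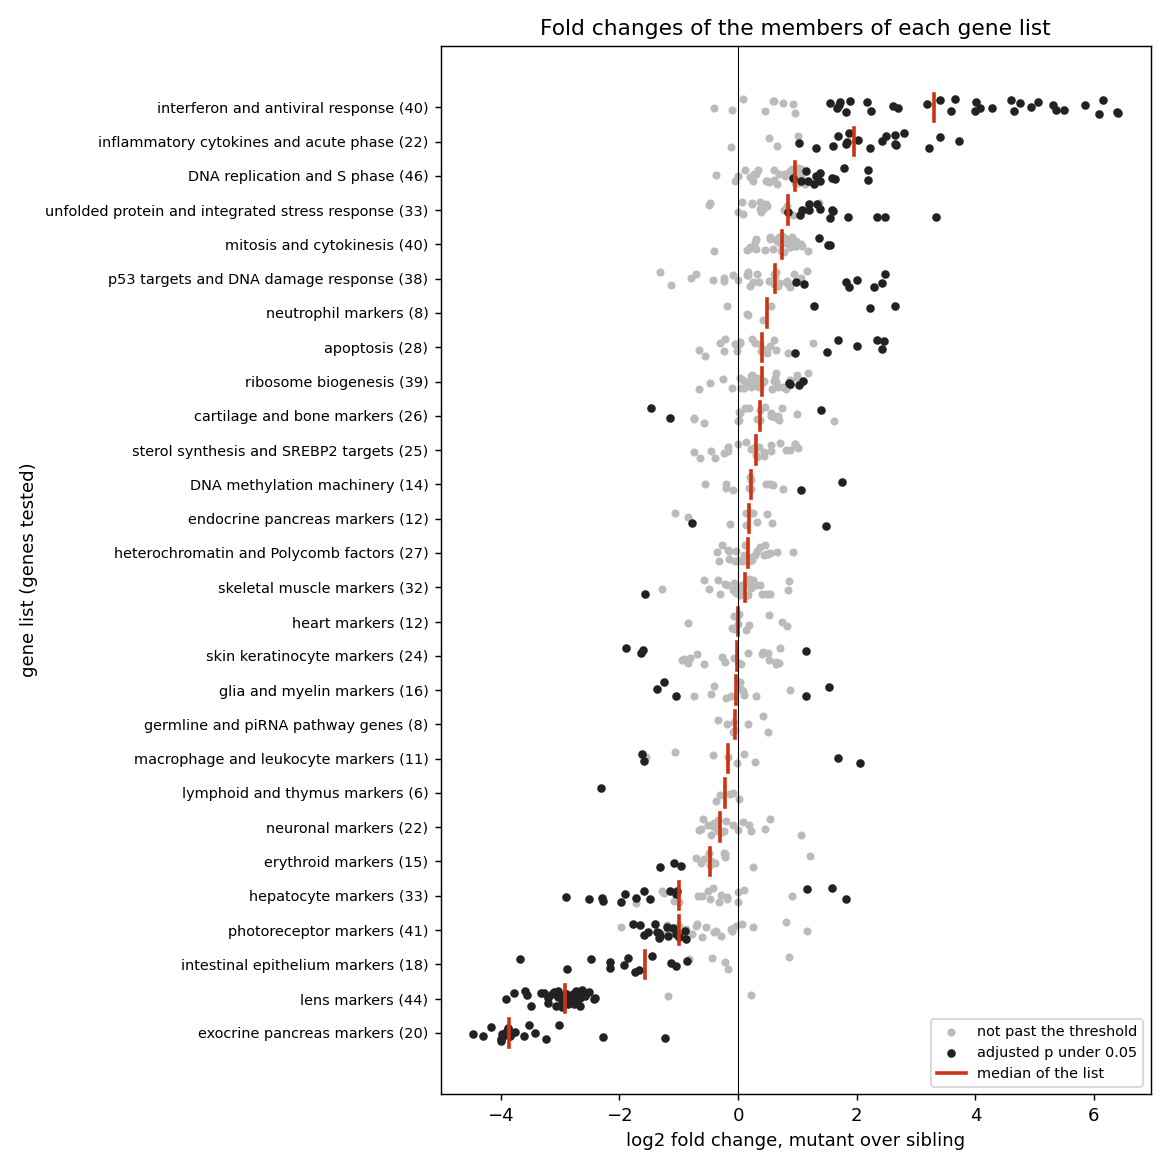
Log2 fold change, mutant over sibling, of each tested member of the 28 gene lists, with black points past an adjusted p of 0.05, grey points not past it and a red bar at each list's median. The medians run from -3.86 for exocrine pancreas markers to 3.30 for interferon and antiviral genes.

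Repeats were counted by name, all copies together, and took 13.9 counts per 100 gene counts in sibling 1, 27.5 in sibling 2, 18.7 in mutant 1 and 19.5 in mutant 2. The mutant libraries lay between the siblings, and the difference of the means was -1.59. Without sibling 2 it was 5.19 and without sibling 1 it was -8.37, so the direction turned on 1 sibling library. Long terminal repeat (LTR) elements, which include endogenous retroviruses (ERV), made up 11.2% ± 0.341 (SD, n = 2) of transposon counts in the siblings and 15.5% ± 0.991 (SD, n = 2) in the mutants. ERV elements alone made up 5.41% and 4.95% in the siblings and 7.93% and 8.81% in the mutants. DNA transposons made up 79.8% and 80.5% in the siblings and 76.5% and 75.0% in the mutants. These shares do not use the gene scaling, and their exact permutation tests cannot go under 0.333.

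With the gene table's scaling, in which a repeat's CPM is set against the gene counts, 3 of 1029 repeats tested rose and 2 fell (edgeR adjusted p of 0.05). The internal part of an endogenous retrovirus, ERV4_DR-I, rose from 356 and 495 CPM to 1699 and 2488 CPM (4.92-fold, SE 0.50 on the log2 scale, edgeR adjusted p = 0.00171), a call lost with library totals alone (edgeR adjusted p = 0.115). The Gypsy elements Gypsy11-I_DR (3.63, SE 0.77) and Gypsy163-LTR_DR (3.46, SE 0.82) rose from under 2 CPM in each sibling; the first lost its call without sibling 2 (edgeR adjusted p = 0.0618) and the second with library totals alone (edgeR adjusted p = 0.0836). The simple repeats (CCTCTT)n (-3.31, SE 0.55) and (CGAGCAG)n (-3.58, SE 0.91) fell. Both lie outside the rule for named repeats and were chosen after their values were seen. The call of (CGAGCAG)n was lost with library totals alone, DESeq2 (adjusted p = 0.431), the repeats' own totals, genes and repeats in one table, and without any 1 of the 4 libraries. With the repeats' own totals and TMM, the split was 17 higher and 1 lower, with 4 calls shared by both scalings. Of those 17, 16 were LTR elements and 4 of these ERV. The scalings put the median log2 fold change of all repeats at -0.15 and -0.01, the first of which was -0.49 without sibling 1 and 0.28 without sibling 2. With mutant 1 or mutant 2 left out, no repeat passed in edgeR (unadjusted p under 0.05 for 10 without mutant 1 and 6 without mutant 2), and without sibling 1, whose removal leaves the repeat-rich sibling 2 alone, 386 repeats were lower and 23 higher. Without sibling 2, 14 were higher and 1 lower.

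As classes, tested among genes and repeats together, DNA transposons were lower (median log2 fold change -0.22, camera adjusted p = 0.00512, adjusted p = 0.947 with an estimated correlation) and LTR elements did not pass (median 0.07, camera adjusted p = 0.0861, adjusted p = 0.947 with an estimated correlation). LINE, SINE, RC (Helitron) and satellite classes did not pass. The direction turned on sibling 2: without it DNA transposons were higher (median 0.20, camera adjusted p = 0.00544), as were LINE (camera adjusted p = 0.00544) and LTR elements (median 0.53, camera adjusted p = 7.68e-11). Without sibling 1, 5 of the 6 classes were lower, with medians of -0.57 for DNA transposons and -0.25 for LTR elements (camera adjusted p = 0.0116), and without mutant 2 the LTR median was 0.03. Against other repeats alone with their own scaling, LTR elements were higher (median 0.21, camera adjusted p = 1.73e-15, adjusted p = 0.118 with an estimated correlation) and DNA transposons lower (median -0.07, camera adjusted p = 1.96e-09, adjusted p = 0.136 with an estimated correlation). Both of these calls held without any 1 library, and satellites were also lower without sibling 1 (camera adjusted p = 0.00189). Sibling 2's repeat counts per gene count, 1.98 times those of sibling 1, enter each of the gene-scaled values.

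**Figure D3:**
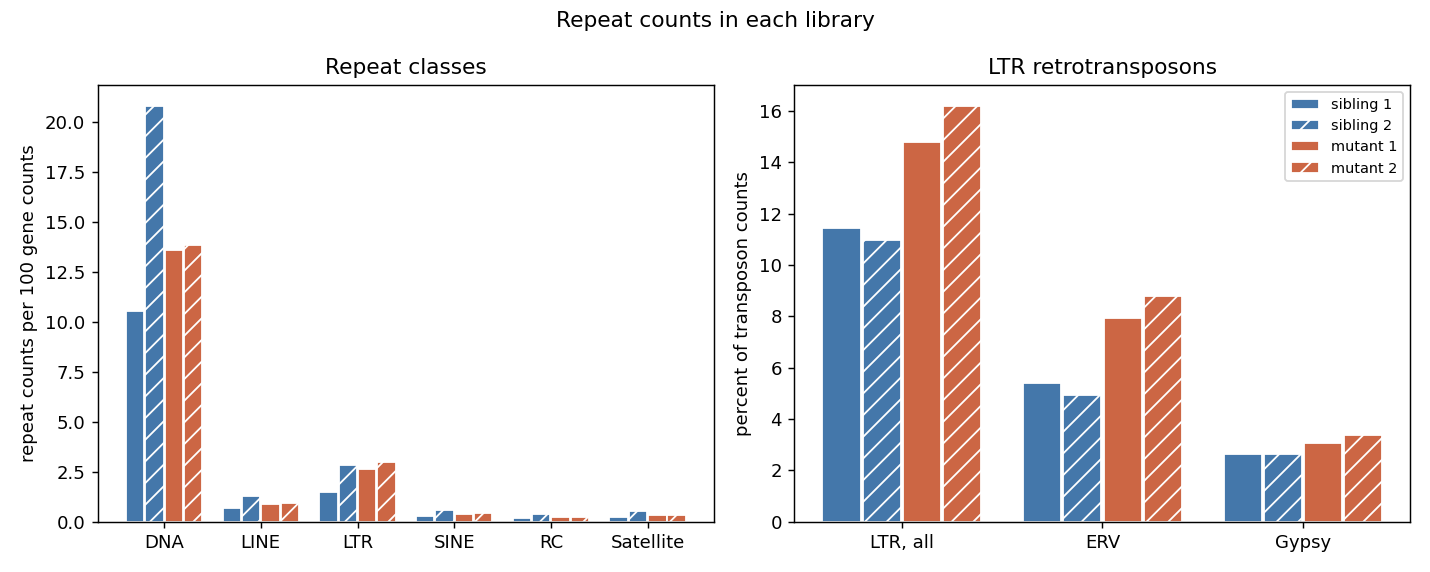
Left, counts of 6 repeat classes per 100 gene counts, and right, LTR elements and their ERV and Gypsy families as percent of transposon counts, 1 bar per library with siblings in blue, mutants in orange and replicate 2 hatched. Sibling 2 has the tallest DNA transposon bar, and the LTR share is 14.8% and 16.2% in the mutants against a mean of 11.2% in the siblings.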

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

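The LTR share alternatives, the class tests on repeats alone and without each library, the list members' calls without each library or with other scalings, and own scaling with the replicate block were chosen after seeing the data. Gene counts stayed within 1.5 times the reported 585 higher and 485 lower under 3 other scalings, DESeq2 (554 and 480, 930 of the calls shared, no adjusted p for 1126 genes), limma-voom, both filters and the 2-fold criterion. Leaving out 1 library, where the lone library is assumed to vary like the other group's, gave 333 to 805 higher and 243 to 754 lower. The cause was not tested. Gene lists passed in 8 to 12 cases higher and 5 to 8 lower without 1 library, against 9 and 6. With an estimated correlation 0 and 0 lists passed, a setting that missed the planted list in every simulation, and fry gave 4 and 3. The estimates ran from -0.116 for neutrophil markers to 0.824 for mitosis, with 0.753 for exocrine pancreas, 0.662 for lens and 0.415 for S phase. The preset of 0.01 makes camera's p too small for lists whose genes vary together. Neutrophil markers had under 5 members at 50 counts and could not be tested there. The reversed values were all for genes not past the threshold: *ccr9a* (-1.02 to 1.22) and *sycp1* (-0.48 to 0.22) were highest without sibling 1, *uhrf1* (-0.69 to 0.44) and *dmrt1* (-1.16 to 0.0176) without sibling 2, and *tox* (-0.29 to 0.007) without mutant 1. Of the named genes, DESeq2 lost 6 calls, among them *cela1.3* (adjusted p = 0.330), library totals alone lost 2, and leaving out mutant 2 lost 26.

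Repeat calls, 3 higher and 2 lower as reported, depended on the scaling and the tool. They were 1 and 1 with library totals alone, 8 and 1 with DESeq2, 10 and 2 with limma-voom, 3 and 1 with no filter, 2 and 1 with at least 50 counts in 2 libraries, 17 and 1 with the repeats' own totals and TMM, 14 and 1 with genes and repeats in one table, and 3 and 0 with simple and structural RNA repeats left out, where the called simple repeats are not tested. Without 1 library they ranged from 0 to 23 higher and from 0 to 386 lower. Against 1 repeat class past the threshold as reported, 0 passed with an estimated correlation, 2 on repeats only with own scaling, and 0 there with an estimated correlation. Without 1 library, 1 to 5 passed. The repeat counts per 100 gene counts, mutant minus sibling, ranged from -8.37 to 5.19 without 1 library. The LTR share, mutant minus sibling, was 4.29 percentage points, 3.15 without the LTR name that gained most, and 3.59 to 4.99 without 1 library. The causes were not tested.

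Mutant and sibling libraries share replicate numbers, and nothing in the labels says that a number marks a clutch. Deviations of same-numbered libraries from their group means correlated at 0.242 across genes and 0.219 across repeats, and genes are not independent replicates. With the replicate block, 1366 genes were higher and 1165 lower, 2 repeats were higher and 2 lower (ERV4_DR-I, with a log2 fold change of 2.29, did not pass, adjusted p = 0.199), 9 lists were higher and 6 lower, and 2 repeat classes passed, LTR elements among them (camera adjusted p = 0.0276). Among list members, those higher with the replicate block came to 27 of S phase, 26 of mitosis, 15 of p53 targets, 11 of ribosome biogenesis, 7 of cartilage and bone, 5 of skin, 3 of sterol synthesis, 2 of photoreceptors, and 1 each of heart, muscle, intestine, and heterochromatin and Polycomb. Those lower came to 29 of photoreceptors, 19 of hepatocytes, 7 of skin, 3 of p53 targets, 2 each of sterol synthesis, endocrine pancreas and muscle, and 1 each of neuronal markers, apoptosis and ribosome biogenesis. The other lists' counts stayed within 1.5 times those reported. Own scaling with the replicate block gave 62 repeats higher and 23 lower.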

Other observations

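The tests of repeat class ratios, of the LTR share without sibling 2 and of the muscle median were chosen only after the result was seen. The gene families were also chosen after their values were seen, taken by patterns in their symbols, and have no test as groups. Of 14 MHC and peptide loading genes tested, 9 rose and 5 did not pass, and *b2m* and *tap2a* also stand in the interferon list. *cd74b*, a second invariant chain gene, went from 7.67 and 8.49 CPM in the siblings to 242 and 189 CPM in the mutants, and the peptide transporter gene *tap2a* from 1.58 and 1.89 to 47.5 and 46.3 CPM. The class I genes *mhc1laa* and *mhc1zda* had log2 fold changes of -0.26 (SE 0.25) and 0.18 (SE 0.23) and did not pass. Of 22 proteasome core subunit genes, 9 rose, among them *psmb12* (5.19, SE 0.52) and *psmb9a* (4.94, SE 0.52), while *psmb6* and *psmb7* had 0.37 (SE 0.34) and 0.03 (SE 0.28). The proteasome activator genes *psme1* (2.91, SE 0.22) and *psme2* (3.64, SE 0.26) rose. *mhc1zba* differed within groups, at 42.8 and 4.09 CPM in siblings 1 and 2 and 25.0 and 0 CPM in mutants 1 and 2.

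Of 13 *her* genes, which encode Hairy-related repressors that include Notch targets, 5 fell and 8 did not pass. *her4.2* fell by 1.99 (SE 0.27) and *her2* by 1.86 (SE 0.35) on the log2 scale. The *her4* copies are near-identical, so their single values are uncertain. Of 6 secretory calcium-binding phosphoprotein genes tested, a family of tooth and bone matrix genes, 5 fell, with *enam* at -2.26 (SE 0.28) and *scpp9*, the furthest, at -3.39 (SE 0.79), while the osteopontin gene *spp1* had 0.74 (SE 0.24) and did not pass.

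The repeat excess of sibling 2 over sibling 1, scaled by genes, ran from 1.58 to 1.82 between the DNA, LINE, LTR, SINE, RC and satellite classes, a highest to lowest ratio of 1.156. The ratio was not uniform across all repeats: per gene count, without the TMM factors, it was 2.55 for simple repeats and 0.678 for structural RNA, against 1.98 for DNA transposons. The tenth of genes with the lowest CPM had a median log2 ratio of 0.0584 between these libraries, between the bounds of 0 and 0.2 set for it. The simple repeat (CCTCTT)n stood at 167 and 93.7 CPM in the siblings and 19.2 and 6.33 CPM in the mutants.

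LTR elements took a larger share of transposon counts in the mutants. The difference remained without sibling 2, as the lower mutant share was 1.293 times that of sibling 1 alone. That comparison was chosen with the shares known, so it is no independent test of sibling 2's repeat excess as the source. A single abundant element is argued against: without ERV1-N5-LTR_DR, the LTR name that gained most counts, the lower mutant share was still 1.264 times the higher sibling share. The mutant genotype and reads placed among related copies stay open, and the latter was not tested. A rise of LTR transcription in the mutants is a hypothesis from these same 4 libraries.

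The rise of interferon genes may reflect more leukocytes in the mutant pools. That would raise leukocyte markers by a comparable amount. The 19 neutrophil and macrophage markers together had a median log2 fold change of 0.1472, against 3.30 for the interferon list. The SE of the marker median, 0.245, comes from the spread across the 19 markers and does not measure the spread between pools. The most abundant of them, *mpeg1.2* (2.06, SE 0.23) and *mpx* (2.22, SE 0.24), rose. So did *cyba* (1.29, SE 0.27), *ctss2.1* (1.68, SE 0.33) and *mmp13a* (2.64, SE 0.55), while only *mpeg1.1* and *coro1a* fell past the threshold. Of the 19, 11 had a fold change above 0, and 1 stands in another list. Over these 19 markers the values argue against a gain of both cell types as the whole source. Single markers moved both ways, so their median is no count of cells. *cd83*, described above as a protein of antigen-presenting cells, is outside the marker lists and rose by 6.32 (SE 0.30). More cells of one type, or a change of expression within leukocytes or other cells, stays open.

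The falls of exocrine pancreas and lens markers may come from one rate of loss of differentiated tissue that lowers every organ's markers alike. The bound set before the list values were seen asked for at least 2 of the hepatocyte, intestine, muscle and photoreceptor medians to lie above -0.5 by more than 2 standard errors, and 1 did, so that test left the explanation undecided. The median of the list that did, skeletal muscle, was taken as a test of its own only after this outcome. It was 0.1085, with an SE of 0.0619 from the spread across its genes, and ran from -0.12 to 0.37 without 1 library. Loss in every organ alike was set to need a value below -0.5, and the muscle median shows no such fall. Because that test was picked after the planned one came out undecided, with its value known, it gives no verdict on the explanation. Neither test asked whether the falls were of one size. Set side by side after the values were seen, the medians were -3.86 for exocrine pancreas, -2.92 for lens and -0.995 for photoreceptor markers. Without 1 library they ran from -5.95 to -3.07, from -3.31 to -2.31 and from -1.02 to -0.91. The photoreceptor range lies apart from the others, so photoreceptor markers fell less in these libraries. These ranges come from overlapping sets of libraries and do not measure the spread between pools. The comparison was picked with the values known, so it is no test of one rate for every organ. That explanation stays undecided. Losses that differ between organs, or a delay in organs that differentiate late, stay open and were not tested.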
